A study of Mus musculus with 2 samples.

How the data were processed

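Mature olfactory sensory neurons expressing the odorant receptor gene Olfr16 (also called MOR23) were sorted by flow cytometry from the olfactory epithelium of adult MOR23-GFP mice of both sexes, per the labels. In situ Hi-C, which ligates DNA ends that lie close together in the nucleus and reads the ligated pairs, was run on 28000 sorted cells for biological replicate 1 and 24400 cells for biological replicate 2, with DpnII as the restriction enzyme and 1% formaldehyde as the fixative. The 2 replicates form 1 group.

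The values used here are 1 list of boundaries, that is, positions that separate stretches of chromosome with many internal contacts. Per the series design text, the authors called the boundaries on a contact matrix made from the contact lists of both replicates combined, on the GRCm38 assembly, which the submitters' processing notes also name. Each deposited boundary is an interval of 5 kb with a class, Weak or Strong, and a strength score given by the authors' caller. The score's formula, the caller, its window, the aligner and the filters are not given in the sources used here, so the deposited score was used only to describe, rank and split boundaries within this list. In the file, all Strong boundaries score at least 0.500 and all Weak boundaries score lower, and no boundary scores under 0.200. Contact matrices, contact lists, insulation tracks and compartment tracks were not used here. The list carries no value per replicate and no read depth. The depth behind each boundary is therefore unknown, no spread between replicates can be given, and every test below places the pooled list against the genome. Exact 95% intervals (Clopper-Pearson) cover counting error only.

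Gene positions came from GENCODE release M21 and sequence from the reference genome of the same assembly. Boundary coordinates were checked against chromosome lengths, and each lay within its chromosome. Coordinates are 1-based. The annotation held 53843 genes on the 20 chromosomes of the list, 21755 of them protein-coding. A gene start was the 5′ end of the gene, and 1 start was taken per gene. A start counted as near a boundary when it lay within 10 kb of the boundary interval, counted in bins of 5 kb.

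Placement was tested against 10000 circular shifts. All boundaries of a chromosome were moved together by a random distance of at least 200 kb, on the stretch from its first to its last boundary closed to a circle. Spacing and number of boundaries are kept by this shift. Shifts permute positions and random lists permute list membership, so their p-values are called permutation p-values, as are those from boundaries moved alone. The two-sided p was (1 + hits)/(1 + shifts), so 0.0001 was the smallest p possible. Expected values are means over the shifts, and ratios are observed over expected. In all, 18 gene lists were fixed before the data were examined, and their p-values were adjusted by Benjamini-Hochberg over the 18 lists. Gene starts outside the first to last boundary, 211 of the protein-coding ones, were left out. Each list was also set against 10000 random lists of protein-coding genes of the same size; for tandem families, whose members are neighbours, that p is only a description. The histone list was defined by name and also took in H13, a histocompatibility gene that is no histone.

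Clusters of a gene family were runs of at least 5 genes with gaps of at most 500 kb. Boundaries per Mb inside clusters and the share of cluster ends within 25 kb of a boundary were tested with the same shifts. Scores inside and outside clusters were compared by 100000 permutations of the score among boundaries of the same chromosome. The CTCF consensus CCASYAGRKGGC was searched on both strands, with 1000 shifts and 20 seeded permutations of its letters as controls; permutations that could hold a CG pair were not used. Orientation was tested on matches within 50 kb of boundary midpoints. The plan called for mirroring all matches of a boundary together. A mirror that swaps side and strand at once leaves the statistic unchanged, so the strands of all matches of a boundary were turned together instead, in 100000 random draws. Strong and Weak boundaries were compared by 100000 permutations of the class within chromosomes, adjusted over 3 features. X was compared with the 19 autosomes by an exact permutation over chromosomes, whose smallest p is 0.05.

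Genes were named by a rule fixed before the data were examined. It took Olfr16, every gene of the olfactory sensory neuron list within 10 kb of a boundary and the 5 farthest, and the nearest protein-coding gene, up to 50 kb away, to each of the 10 highest-scored boundaries. It also took up to 4 genes nearest to a boundary from each other list past the threshold, with ties broken by score, and the first and last gene of the 3 largest olfactory receptor clusters. Other genes are said to have been chosen after their values were seen.

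Repeated sequence was measured as the share of 50 bp words, sampled every 50 bp, that occur once in the chromosomes, averaged over 105 kb; unread bases counted as not unique. The tests of gene starts, gene lists, cluster density, cluster ends, cluster score and CTCF consensus orientation were run on simulated placements of the 7435 boundaries; the other tests were not. With shifted sets that held no relation, 3.28% of 1800 list tests and 5 of 100 gene-start tests gave p under 0.05; for cluster density, ends and score the counts were 6, 4 and 6 of 100, and for orientation 1 of 100. With planted relations, each of the 6 kinds of test passed in 100 of 100 sets. The shifted sets were made by the same kind of shift as the null of the placement tests. They therefore check the calculation and not whether that null suits regional gene density or repeats. For lists and clusters, relations were planted only in ribosomal protein genes and olfactory receptor clusters. Weaker relations were not planted, so power for them or for shorter lists was not measured. Word counts were the same as direct counting in all 400 positions compared.

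Alternatives used only Strong boundaries, overlap with the boundary itself or a distance of 25 kb, autosomes only, starts of genes of any biotype, other cluster definitions, a shorter consensus, a 20 kb window for orientation, quartile groups of the score, and a null in which each boundary moved alone by 100 to 500 kb (1000 draws), which keeps regional gene density; score differences in clusters used 10000 permutations there. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0; plots used matplotlib 3.10.9.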

Results

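In situ Hi-C was performed on 2 biological replicates of sorted mouse olfactory sensory neurons that express Olfr16, 28000 and 24400 cells. The measurements are 7435 chromatin boundaries, each 5 kb wide, called by the authors on both replicates combined across chromosomes 1 to 19 and X of GRCm38. There is 1 cell population and no second group, so the comparisons are between boundaries and the genome, between chromosomes and between the authors' 2 classes. The list gives no replicate values for any boundary, and p-values below measure placement along the genome or differences within the list, not variation between animals.

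Strong boundaries made up 51.8% of the list (3854 of 7435, exact 95% interval 50.7 to 53.0%) and Weak boundaries the other 3581. The median score was 0.520, with quartiles at 0.301 and 0.969. Adjacent boundaries lay a median of 265 kb apart (quartiles 185 and 400 kb), and Strong boundaries alone lay a median of 400 kb apart. Among 7415 intervals, 227 were longer than 1 Mb and the longest was 11.7 Mb. The highest score, 4.38, belonged to the boundary at chromosome 1, positions 88305001 to 88310000, which overlaps an exon and untranslated sequence of Trpm8, the cold and menthol channel; the gene's start lay 27.3 kb away. The next, with a score of 3.91, lay on chromosome 11 at 3195001 to 3200000, in an intron of Drg1 and an exon of the pseudogene Fau-ps2 (both chosen after their values were seen) and 1.54 kb from the start of Sfi1, a centrosome protein gene. The third was a boundary on chromosome 2 (37350001 to 37355000, score 3.33) in exonic sequence of Pdcl, whose start was 4.33 kb away. The remaining boundaries of the 10 highest had scores from 3.17 to 3.25. Their nearest gene starts were those of Trrap, within the boundary, Fstl5 at 4.27 kb, Gm527 at 12.9 kb, Jrkl at 20.8 kb, 4930467E23Rik at 24.6 kb and Ppp2r5c at 37.1 kb. The boundary nearest to 4930467E23Rik, on chromosome 8 (19700001 to 19705000), borders an interval of 2.27 Mb without a boundary. Only 27.4% of sampled 50 bp words in that interval were unique. The boundary on chromosome 7 (92090001 to 92095000) had no protein-coding start within 50 kb and lay in an intron of Dlg2, a gene chosen after its value was seen.

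Because mice of both sexes were pooled, X was present at fewer copies than the autosomes, and its boundaries were compared with theirs. X had the lowest median score, 0.346, against 0.538 ± 0.056 (SD over 19 autosomes, range 0.453 to 0.661). This difference of -0.192 gave p = 0.05 in the two-sided exact permutation over chromosomes, which is the smallest that this test can give and does not fall under the 0.05 threshold. Only 121 of 400 X boundaries were Strong (30.2%, exact 95% interval 25.8 to 35.0%). X also had the lowest density, 2.49 boundaries per Mb against 2.96 ± 0.20 (SD over 19 autosomes), with an exact permutation p = 0.1. In sequence with a unique share of at least 60%, the density was 2.82 per Mb on X and 3.02 per Mb over all autosomes together. Chromosome 11 was at the other end, with 3.45 boundaries per Mb, a median score of 0.661 and 60.9% Strong boundaries (exact 95% interval 56.0 to 65.6%).

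**Figure D1:**
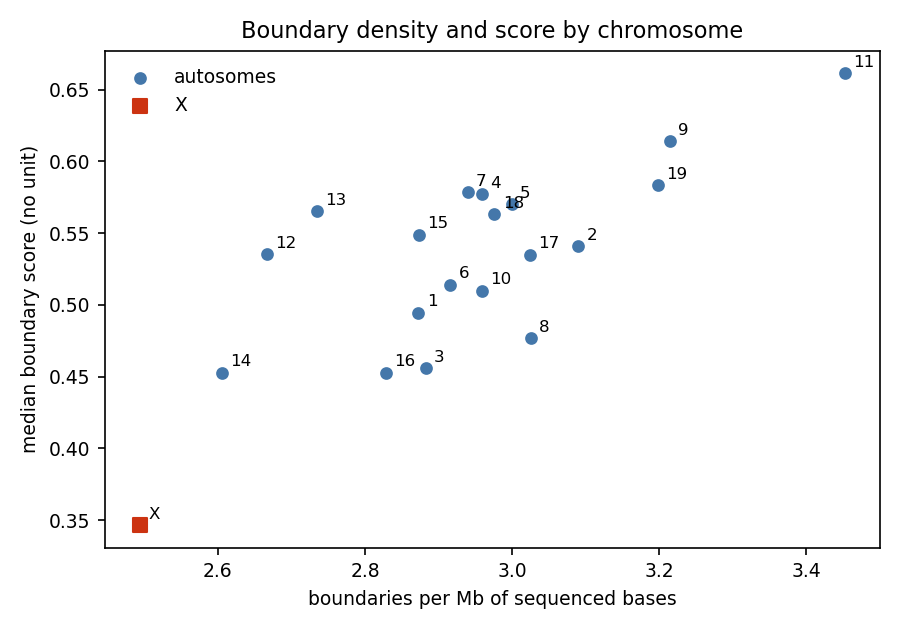
Each point is a chromosome, with boundaries per Mb of sequenced bases on the horizontal axis and the median deposited score, which has no unit, on the vertical axis. X (square) lies below the 19 autosomes (circles) at 2.49 boundaries per Mb and a median score of 0.346, and chromosome 11 lies at the upper right with 3.45 and 0.661.

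Boundaries lay at gene starts more often than shifted boundaries. A protein-coding gene start was within 10 kb of 2067 of 7435 boundaries, 27.8% (exact 95% interval 26.8 to 28.8%), where the shifts gave 17.0% (95% range 16.2 to 17.8%). The ratio was 1.64, with a two-sided permutation p = 0.0001, the smallest that 10000 shifts can give. Seen from the genes, 2689 of 21544 protein-coding starts (12.5%) were within 10 kb of a boundary, against 7.37% for the shifts.

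Of the 18 gene lists, 6 lay near boundaries more often than the shifts at an adjusted p under 0.05 and 0 less often; without adjustment these counts were 7 and 1. The highest share belonged to ribosomal protein genes, of which 29 of 83 starts (34.9%, exact 95% interval 24.8 to 46.2%) were within 10 kb, a ratio of 4.71 with an adjusted p = 0.0009. Rps24, Rpl3l, Rpl9 and Rpl26 started inside Strong boundaries with scores of 2.78, 1.44, 1.00 and 0.897. Rps24, Rpl9 and Rpl26 encode ribosomal subunit proteins, and Rpl3l is a muscle paralogue of such a gene. Proteasome genes followed with 13 of 44 starts (29.5%, ratio 3.98, adjusted permutation p = 0.0009). Among these, Psmc4 and Psme3 started inside a boundary, and Psmc1 and Psmb7 at 0.154 and 0.914 kb from one. Mitochondrial ribosomal protein genes had 16 of 78 starts near boundaries (20.5%, ratio 2.74, adjusted permutation p = 0.0024), with Mrps27, Mrps10, Mrps23 and Mrpl12 inside Strong boundaries. For genes of respiratory complex I, the entry enzyme of the mitochondrial electron chain, 9 of 46 starts were near (19.6%, ratio 2.65, adjusted permutation p = 0.029). Ndufaf2 and Ndufb2 started inside boundaries, and Ndufb10 and Ndufaf5 at 0.523 and 0.649 kb; the boundary next to Ndufb10 is the one that holds the start of Rpl3l.

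Genes that act in mature olfactory sensory neurons were near boundaries in 7 of 32 cases (21.9%, exact 95% interval 9.28 to 39.97%), where the shifts gave 7.32%, a ratio of 2.99 with an adjusted p = 0.029. The 7 included Gng13, a G protein subunit of olfactory signalling, whose start at position 25717171 of chromosome 17 lay inside a Strong boundary scored 0.928. The transcription factor gene Emx2 lay 3.37 kb from a boundary scored 2.57 on chromosome 19, in an intron of the antisense gene Emx2os, which was chosen after its value was seen. Ebf1, another transcription factor of these neurons, was 7.32 kb from an intergenic Strong boundary scored 1.42. The axon guidance genes Nrp1 and Plxna1 were 3.60 and 7.38 kb from Strong boundaries scored 0.960 and 0.559. Ncam1, a cell adhesion gene, and Umodl1 lay 1.08 and 9.64 kb from Weak boundaries scored 0.289 and 0.415. At the far end were Atf5 (303.3 kb from the nearest boundary), Reep1 (217.4 kb), S100a5 (136.5 kb), Ric8b (107.4 kb) and Pde1c (94.1 kb). Neither 15 genes of progenitors and immature neurons nor 18 genes of non-neuronal cells of the epithelium had a start within 10 kb; a count of 0 allows up to 20% and 16.7% by 3 counts of the total, and up to 21.8% and 18.5% by the exact 95% interval. The adjusted permutation p was 0.49 for both. Genome architecture genes, among them genes for insulator, cohesin, lamina and heterochromatin proteins, were near in 6 of 26 cases (23.1%, ratio 3.17, adjusted permutation p = 0.029). Ehmt1 and Mau2 started inside Strong boundaries and Pds5a and Hmgb1 inside Weak ones.

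Other settings ended part of these calls. When each boundary was moved alone by 100 to 500 kb, the ratio was 2.49 for olfactory sensory neuron genes (adjusted permutation p = 0.072), 1.90 for complex I genes (0.11) and 2.54 for architecture genes (0.078). When starts had to overlap the boundary itself, 2 proteasome genes (ratio 3.10, adjusted permutation p = 0.39), 2 complex I genes (2.94, 0.39) and 1 olfactory sensory neuron gene (2.12, 0.67) were left. Architecture genes then had 4 of 26 starts inside a boundary (ratio 10.5, adjusted permutation p = 0.0054), but were not called with Strong boundaries only (ratio 2.07, 0.48) or within 25 kb (1.68, 0.26). Against random lists of protein-coding genes, ribosomal protein genes (adjusted permutation p = 0.0009) and proteasome genes (0.0083) stood above, and the adjusted p was 0.075 for mitochondrial ribosomal protein genes, 0.25 for complex I genes, 0.19 for olfactory sensory neuron genes and 0.21 for architecture genes. Olfactory receptor genes (adjusted permutation p = 0.0009), type 1 vomeronasal receptor genes (0.0018) and keratin genes (0.0049) stood below the random lists, which do not keep the neighbourhood of tandem genes.

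The other lists did not pass against the shifts. Histone genes had 15 of 69 starts near boundaries (21.7%, ratio 3.13, adjusted permutation p = 0.051), 1 of which is that of H13, no histone gene, chosen after its value was seen. Olfactory receptor genes had 63 of 1093 (5.76%, ratio 0.762, adjusted permutation p = 0.11), and this list passed within 25 kb, with a ratio of 0.731 and an adjusted p = 0.033. Type 1 vomeronasal receptor genes had 8 of 204 (ratio 0.543, adjusted permutation p = 0.16), type 2 had 6 of 118 (0.688, 0.49) and keratin genes, which encode filament proteins of epithelia and hair, 2 of 110 (0.233, 0.09). Trace amine-associated receptors had 1 of 15 near, bitter taste receptors 4 of 35, Hox genes 5 of 39, zinc finger genes 37 of 423 and cytochrome P450 genes 11 of 94, with ratios from 0.882 to 1.65 and adjusted p from 0.28 to 1. Within 25 kb, type 2 vomeronasal receptor genes (ratio 0.419, adjusted permutation p = 0.02) and cytochrome P450 genes (1.62, 0.039) passed.

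**Figure D2:**
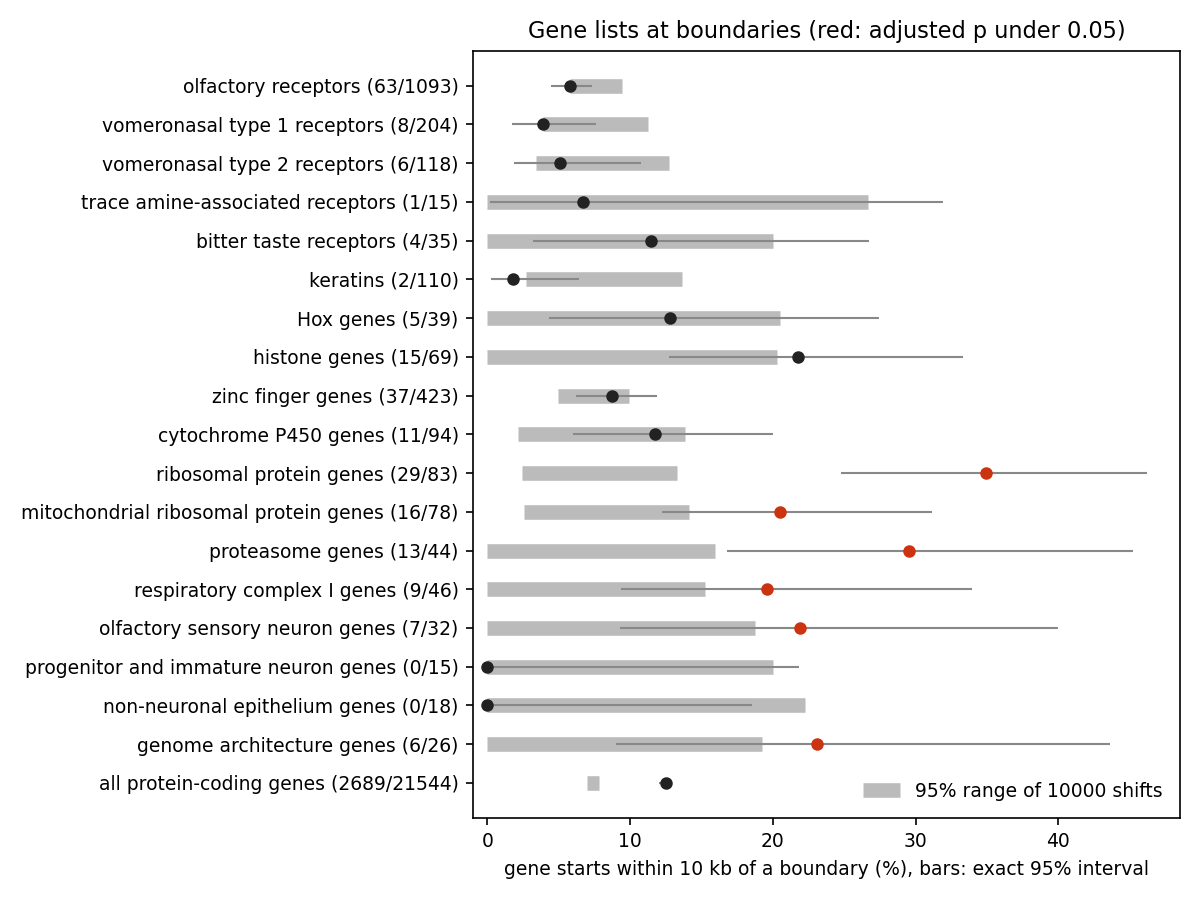
Points give, for each gene list, the percentage of gene starts within 10 kb of a boundary, with exact 95% intervals as thin bars and the number of starts in brackets; thick grey bars give the 95% range of 10000 shifts. Red points mark the 6 lists with an adjusted p under 0.05, led by ribosomal protein genes at 34.9%, and the olfactory receptor genes sit at 5.76%.

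Olfactory receptor genes lie in clusters, and each of these neurons expresses 1 of them, so their clusters were examined as regions. There were 33 clusters with 1054 genes over 30.3 Mb. Cluster ends lay near boundaries more often than under the shifts: 25 of 66 ends (37.9%) were within 25 kb of one, where the shifts gave 16.3% (95% range 7.58 to 25.8%), a ratio of 2.32 with a permutation p = 0.0001, the smallest possible, and 0.0008 after adjustment over 8 families. Inside the clusters there were 78 boundaries, 2.57 per Mb against 3.02 for the shifts (ratio 0.852, permutation p = 0.11, adjusted p = 0.29). Without adjustment over families, the ratio passed with Strong boundaries only (0.667, permutation p = 0.034), gaps of at most 100 kb (0.786, 0.035) and at least 10 genes (0.800, 0.039). It did not pass with gaps of at most 1 Mb (0.905, permutation p = 0.3), with boundaries moved alone (0.885, 0.084) or with autosomes only (0.858, 0.14). Boundaries inside had a mean score of 0.687 and those outside 0.719 (permutation p = 0.37). Strong boundaries made up 42.3% of those inside and 51.9% of those outside, and these shares were not tested. The largest cluster, 217 genes on chromosome 2 from Olfr987 at 85330779 to Olfr1272 at 90292841, held 9 boundaries, 1 of them Strong. Its ends lay 40.8 and 177.2 kb from the nearest boundary. The second, 124 genes on chromosome 7 from Olfr543 to Olfr692 (102476579 to 105369355), held 11 boundaries, 2 of them Strong, and its first end lay 3.42 kb from a Strong boundary scored 2.67. The third, 93 genes on chromosome 9 from Olfr160 to Olfr986 (37708964 to 40190134), held 4 boundaries, and its last end lay 10.1 kb from a Strong boundary scored 2.74. No boundary was inside 5 of the 33 clusters, 4 clusters had both ends within 25 kb of a boundary and 12 had neither.

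Among the other tandem families, both groups of vomeronasal receptor clusters held few boundaries. In 10 clusters of type 1 receptors there were 1.41 boundaries per Mb against 2.91 for the shifts (ratio 0.483, permutation p = 0.0012, adjusted p = 0.0096), and in 9 clusters of type 2 receptors 1.65 against 2.96 (ratio 0.559, p = 0.0027, adjusted p = 0.011). With each boundary moved alone, the ratios were 0.710 (permutation p = 0.052) and 0.805 (p = 0.086). Ends of type 1 receptor clusters lay near boundaries in 9 of 20 cases (45.0%, shifts 15.9%, adjusted permutation p = 0.014), and those of type 2 clusters in 1 of 18. With at least 10 genes per cluster the unadjusted permutation p for type 1 ends was 0.06. Boundaries inside type 1 clusters had a mean score of 0.599 against 0.719 outside (permutation p = 0.32, adjusted p = 0.59). Inside type 2 clusters the mean was 0.465 against 0.719 outside (permutation p = 0.027, adjusted p = 0.22). For clusters of keratin, Hox, histone, zinc finger and cytochrome P450 genes, density ratios ran from 0.806 to 1.87 with adjusted p from 0.31 to 1, and ends were near in 25.0 to 50% of cases with adjusted p from 0.071 to 0.63. Without adjustment, ends of zinc finger clusters (permutation p = 0.027) and histone clusters (0.046) passed. For zinc finger ends this was lost with Strong boundaries only (unadjusted permutation p = 0.59) and gaps of at most 1 Mb (0.07), and the other alternatives gave 0.0025 to 0.031. Histone ends lost it under 4 alternatives (unadjusted permutation p from 0.081 to 0.4). Ends of cytochrome P450 clusters, at an unadjusted permutation p = 0.071, passed with Strong boundaries only (0.007) and within 50 kb (0.0032).

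The expressed receptor gene itself lay close to a boundary. Olfr16 (chromosome 1, 172950409 to 172958357, + strand) started 9.59 kb from a Strong intergenic boundary at 172960001 to 172965000 with a score of 0.846, higher than or equal to 69.4% of the list. On its other side the nearest boundary was Weak (172690001 to 172695000, score 0.419) and 255.4 kb away. Between these boundaries lay 265.0 kb with 3 protein-coding starts, those of Olfr16 and of Crp and Apcs, which encode pentraxins of blood plasma and were named after their values were seen. Among 1093 olfactory receptor genes, 5.58% lay as close to a boundary as Olfr16 or closer, and the median distance was 105.0 kb (quartiles 49.3 and 194.7 kb). The start of Olfr16 is also a cluster end, and 25 of 66 ends of olfactory receptor clusters (37.9%) lay within 25 kb of a boundary. The distance of Olfr16 was not ranked among such ends, so this percentage does not make it unusual for its position. Olfr16 is the first of 6 genes of its cluster, so the boundary separated it from the other 5 genes, which end with Olfr418, chosen after its values were seen. A single locus gives no test.

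**Figure D3:**
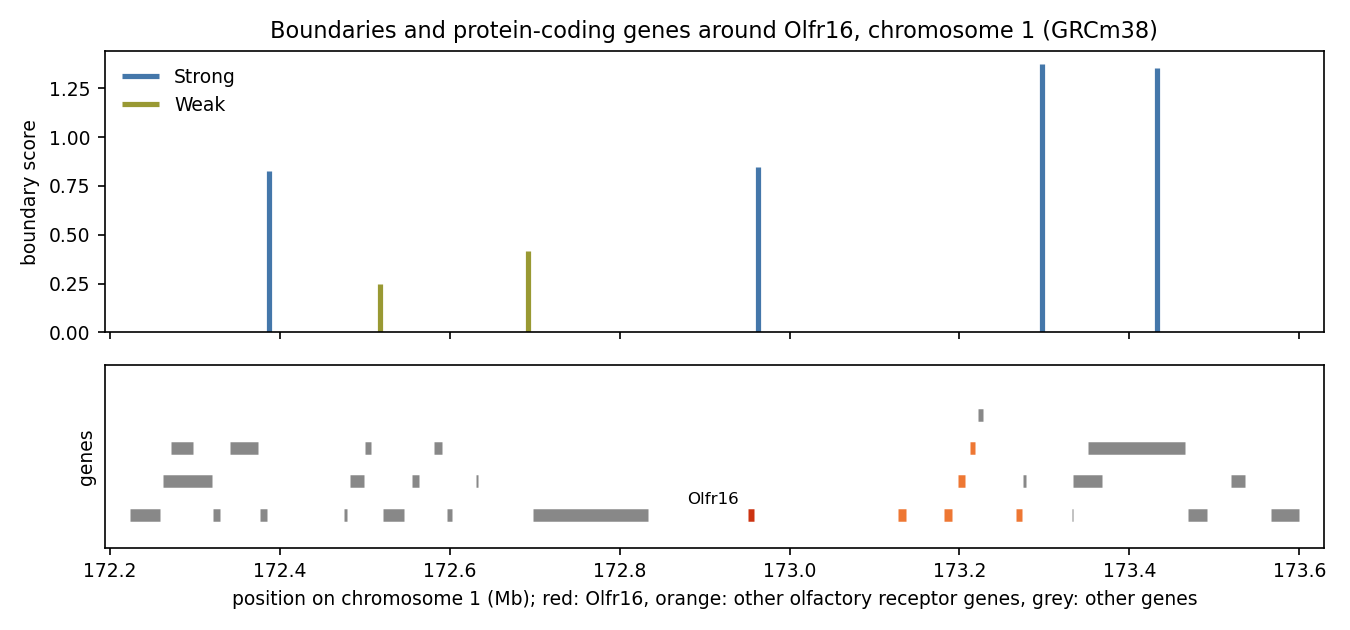
The upper panel gives boundary scores (no unit) against position in Mb on chromosome 1 of GRCm38, with Strong boundaries in blue and Weak ones in olive; the lower panel gives protein-coding genes, spread over rows for legibility. The Strong boundary scored 0.846 lies between Olfr16 (red) and the other 5 receptor genes of the cluster (orange).

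Exact matches to the consensus of CTCF, the insulator protein of mammalian chromosomes, were found within 10 kb of 1719 boundaries, 23.1% (exact 95% interval 22.2 to 24.1%), against 11.1% for shifted boundaries. The ratio was 2.08 with a permutation p = 0.001, the smallest that 1000 shifts can give. The 20 permuted consensus sequences gave ratios from 1.02 to 1.32, 13 of them with p under 0.05, and 0 reached the ratio of the consensus. Matches pointed away from the boundary on both sides when read along the consensus. Within 50 kb, 63.7% of matches on the right were on the + strand, and on the left 35.6%. This difference of 28.1 percentage points, over 3767 boundaries with a match, had a permutation p = 1e-05 when strands were turned at random, the smallest possible.

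**Figure D4:**
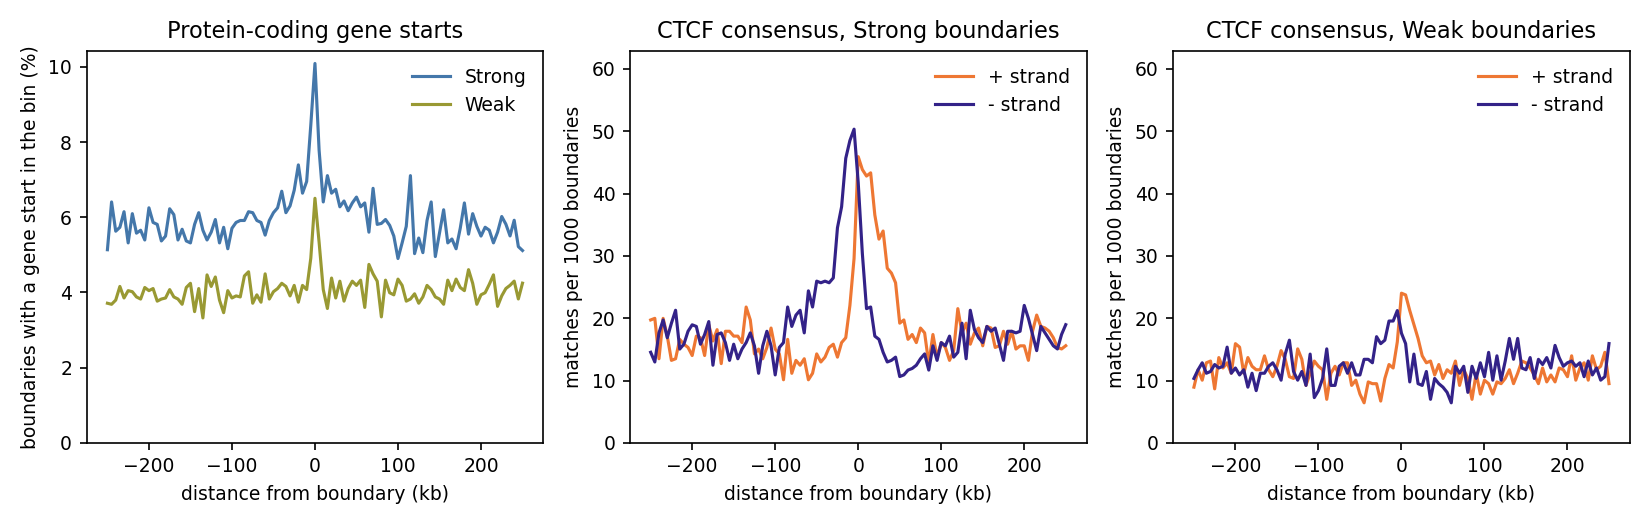
The left panel gives the percentage of boundaries with a protein-coding gene start in each 5 kb bin, against distance from the boundary in kb, for both classes; the other panels give CTCF consensus matches per 1000 boundaries on each strand. Gene starts and matches peak at the boundary in both classes, and for Strong boundaries matches on the - strand peak at 50.3 per 1000 just left of it and those on the + strand at 45.9.

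The authors' classes differed in all 3 sequence features compared. A gene start was within 10 kb of 33.9% of Strong and 21.2% of Weak boundaries, a difference of 12.7 percentage points. A CTCF consensus match was near 30.3% of Strong and 15.4% of Weak boundaries. GC content was 44.2% in Strong and 41.5% in Weak boundaries. Each difference had an adjusted p = 1e-05 by permutation of the class within chromosomes, the smallest possible. Boundaries with both a gene start and a match numbered 555, of which 70.6% were Strong. A further 1164 had a match only (66.7% Strong) and 1512 a gene start only (60.5% Strong). The largest part, 4204 boundaries or 56.5%, had neither, and 42.1% of these were Strong.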

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

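Gene starts at boundaries kept their direction and their side of the threshold under all 6 alternatives (ratios from 1.28 to 2.11). Under the alternatives run for each, so did the CTCF consensus (5 alternatives, 1.52 to 2.68), its orientation (2 alternatives, 26.2 to 32.0 percentage points), the share of olfactory receptor cluster ends near boundaries and the differences between Strong and Weak boundaries. X stayed below the autosomes with Strong boundaries only, at exact permutation p = 0.05 for score and for density. With autosomes only, 53.1% of boundaries were Strong, and Strong boundaries alone lay a median of 400 kb apart. The number of gene lists past the threshold fell from 6 to 3 when starts had to overlap the boundary itself and to 3 when each boundary was moved alone. The list of olfactory sensory neuron genes then had ratios of 2.12 (adjusted permutation p = 0.67) and 2.49 (adjusted p = 0.072), within a range of adjusted p from 0.01 to 0.67 over its alternatives. Overlap leaves 1 of the 32 genes near a boundary; for the moves the cause was not tested. Olfactory receptor genes passed within 25 kb, with a ratio of 0.731. Without adjustment over families, density inside olfactory receptor clusters passed with Strong boundaries only (0.667), gaps of at most 100 kb (0.786) and at least 10 genes (0.800). The cause was not tested. The score difference inside these clusters changed sign among Strong boundaries, to 0.130 (permutation p = 0.21).

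Of 206 alternatives for other lists and families, 168 kept direction and side of the threshold, 16 fell short of it, 7 passed it and 15 changed direction, none of these 15 past the threshold. For lists the side was read from the adjusted p, and for clusters, here and above, from the unadjusted p. With overlap, the list ratios were 1.36 for type 1 vomeronasal receptors, 0.950 for zinc finger genes and 0 for cytochrome P450 genes. Trace amine-associated receptors had 1.73 with Strong boundaries only and 1.21 within 25 kb. Among clusters, the density ratio of histone genes was 0.842 with Strong boundaries only and 0.999 with boundaries moved alone, and that of cytochrome P450 genes 1.10 with gaps of at most 100 kb. Ratios for ends were 0.861 and 0.990 for keratins, with gaps of at most 100 kb and at least 10 genes, and 0.772 for Hox genes within 50 kb. With Strong boundaries only, score differences were 0.0219 for type 2 vomeronasal receptors (main setting -0.255) and 0.213 for cytochrome P450 genes (-0.0332). With gaps of at most 100 kb they were -0.379 for histone genes (main setting 0.0355) and 0.0741 for cytochrome P450 genes. The zinc finger score difference, -0.106 in the main setting (permutation p = 0.1, adjusted p = 0.4), kept its direction. Without adjustment, it passed with Strong boundaries only (-0.247, permutation p = 0.014) and gaps of at most 100 kb (-0.313, 0.017) or 1 Mb (-0.111, 0.031). It did not pass with autosomes only (permutation p = 0.11) or at least 10 genes (0.086). The cause of these changes was not tested.

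Leaving out each replicate could not be run, because the list has no value per replicate. No paired analysis was possible because the study has 1 group. Read depth is unknown here, and with it the number of boundaries that deeper data would add.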

Other observations

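The tests of gene biotypes, the comparison of cell-type lists, the tests of repeated sequence in vomeronasal receptor clusters, that of olfactory receptor clusters in unique sequence, the comparison of cluster ends between families and the bootstrap interval of X were chosen only after the result was seen.

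Among genes of other biotypes, antisense genes were near boundaries in 295 of 2947 cases (10.0%, ratio 1.36, adjusted permutation p = 0.0006 over 6 biotypes), microRNA genes in 244 of 2175 (11.2%, ratio 1.54, adjusted p = 0.0075) and small nuclear RNA genes in 129 of 1373 (9.40%, ratio 1.29, adjusted p = 0.0084). Processed pseudogenes had a ratio of 1.10 (adjusted permutation p = 0.018), and lincRNA and small nucleolar RNA genes had ratios of 1.08 (adjusted p = 0.12) and 1.15 (0.3). For all protein-coding genes the ratio was 1.69. Whether protein-coding starts close to genes of these biotypes account for their ratios was not tested. Olfactory sensory neuron genes, 7 of 32 near boundaries, did not pass against progenitor and immature neuron genes (0 of 15) or non-neuronal genes (0 of 18), each with an adjusted p = 0.08 by Fisher's exact test.

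The 10 longest intervals without a boundary lay in repeated sequence, with under 40% of sampled 50 bp words occurring once in the chromosomes. Of 47 intervals between boundaries at least 1.5 Mb apart, 20 had a unique share under 60%, and the others lay in mostly unique sequence. The longest, 11.7 Mb on X from 24140001 to 35835000, had 10.4%. An interval of 3.55 Mb on chromosome 7 (19975001 to 23525000) had 11.1% and held 50 genes named Vmn1r, an interval of 3.295 Mb on the same chromosome (6945001 to 10240000) had 20.1% and held 24 genes named Vmn2r, and an interval of 2.31 Mb on chromosome 4 (59935001 to 62245000) held 22 genes for major urinary proteins. The longest in mostly unique sequence, an interval of 2.235 Mb on chromosome 6 (79645001 to 81880000), with 89.8% unique words, held 2 protein-coding genes, among them Lrrtm4, a synaptic adhesion gene. These regions and genes were chosen after their values were seen. Sequence with a unique share under 30% had 0.0174 boundaries per Mb. Sequence with 30 to 60% had 1.19 per Mb with a median score of 0.371, from 44 boundaries. Sequence with 60 to 80% had 3.91 per Mb with a median score of 0.332. Sequence with 80 to 90% had 2.72 per Mb (median score 0.395), and sequence with over 90% had 3.01 per Mb (0.617).

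Vomeronasal receptor clusters held few boundaries, and repeated sequence, from which reads may not be placed, is a candidate explanation. In sequence with a unique share of at least 60%, both types together had a density ratio of 0.704 to the shifts (permutation p = 0.02). Split after that value was seen, type 1 clusters still had a ratio of 0.624 (unadjusted permutation p = 0.035), against 0.483 in all sequence. This argues against the sequence left out as the whole source of the low density in type 1 clusters. The value rests on 13 boundaries in 6.815 Mb, and moving each boundary alone was not repeated in that sequence. The caller's window is unknown, so an effect of repeated sequence on calls beside it could not be tested. For type 2 clusters the ratio became 0.749, within the range of the shifts (permutation p = 0.15), so repeated sequence stays open there as the whole cause. Low GC content also stays open: against bins of the same GC content in that sequence, both types together had a ratio of 0.860 (95% counting interval 0.588 to 1.21). As a hypothesis, clusters of chemoreceptor genes that are silent in these neurons may lack boundaries. Olfactory receptor clusters, nearly all silent in a given neuron, had a ratio of 0.825 in that sequence (unadjusted permutation p = 0.045), although in all sequence it was 0.852 with p = 0.11. The olfactory receptor ratio was not matched on GC content. Ratios of the families without chemoreceptors in that sequence ran from 0.799 for keratin clusters, with 7 boundaries, to 1.94 for histone clusters.

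Boundaries on X had lower scores, and X differs from the autosomes in sequence. Unique words made up 76.0% of X and 89.4% of the autosomes, and 15.8% of X boundaries had a gene start within 10 kb against 28.5% on autosomes. After matching on the unique share, X lay at -0.0786 from the mean of the autosomes, and after matching on gene start, CTCF match and GC content at -0.0567, compared with -0.192 before; matching on all 4 left 17.1% of the difference. X stayed below every autosome each time (exact permutation p = 0.05, the smallest possible), which meets the bound set beforehand for excluding each explanation. It did not do so by more than its spread: the 95% bootstrap interval of X reached the lowest autosome. Both explanations therefore stay open as the whole cause. The bound cannot exclude either as a part. Matching on the unique share left 40.9% of the difference, and matching on gene start, CTCF match and GC content left 29.6%. Matching also lowered the SD over the autosomes, from 0.0563 to 0.0315 and 0.0220, and to 0.0148 with all 4. These shares therefore overstate how far X moved toward the autosomes relative to their spread. Copy number of X in the mixed-sex pool may also contribute and was not tested.

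Ends of olfactory receptor clusters lay near boundaries more often than under the shifts. Other protein-coding gene starts within 25 kb of the ends could not account for this alone. Among 41 ends with no other protein-coding gene start within 25 kb, 36.6% were near a boundary against 16.1% for the shifts (permutation p = 0.0012). This argues against starts within 25 kb of the end as the whole cause. A boundary near an end can also lie close to a start more than 25 kb from that end. Such starts, and starts of other biotypes, were not left out and stay open. Edges of repeated sequence stay open: leaving out sequence with a unique share under 60% kept 98.4% of the cluster sequence and all ends, with the same 37.9% near a boundary, so it could not test this. Whether the pattern belongs to olfactory receptor clusters in particular stays open: 29.8% of 114 ends of the other 7 families were near a boundary (Fisher's exact p = 0.32). The position of these ends at changes of compartment or base composition was not tested.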
